A study of Hyphopichia burtonii and Hyphopichia pseudoburtonii with 16 samples.

How the data were processed

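RNA-seq values of each species came in a gene table of their own, with 8 libraries of H. burtonii and 8 of H. pseudoburtonii harvested before and 5, 15 and 30 min after salt and fresh medium were added. Per the submitters' processing notes, reads were handled with CASAVA 1.8.2, FastQC 0.11.8, TopHat2 2.1.1 and Cufflinks 2.2.1, without their order or settings. The values are FPKM as deposited by the authors, with no counts. The genome build and the annotation are not given in the sources used here, so coordinates are printed as the files give them, and gene names are those the files credit to Swiss-Prot.

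The fits were made in R 4.3.3 with the data.table package (1.17.8) and limma 3.58.1, and tables and figures with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. FPKM were turned into log2(FPKM + 1), and genes with FPKM of at least 1 in at least 2 of the 8 libraries of a species were kept, 6047 in H. burtonii and 5798 in H. pseudoburtonii. Each species had its own limma fit with a group per time and a trend in the prior variance. A gene counts as called, and as having risen or fallen, where the p-value adjusted by Benjamini and Hochberg's method over all tested genes was under 0.05. Each later time was compared with 0 min and each with the harvest before it. The comparisons against 0 min share the 0 min libraries.

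Genes were paired between the species by Swiss-Prot accession (3235 pairs) or else gene name (180 pairs), each found once in each species. Such pairs may join paralogs, and genes whose accession and name recur within either species were left out. Of the 3415 pairs, 3399 were tested for the change in H. pseudoburtonii minus that in H. burtonii. Such a difference is a difference between 1 strain of each species in separate library series.

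The 30 tested gene lists, written by name before the data were examined, were tested with camera at an inter-gene correlation of 0.01, for lists of at least 5 measured genes, and again with an estimated correlation and with fry. They cover glycerol, sugar alcohols, the Hog1 pathway, sodium and potassium transport, calcineurin, trehalose and glycogen, oxidative stress, chaperones, ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, translation factors, glycolysis, the TCA cycle, respiration, the pentose phosphate pathway, sugar transporters, ergosterol, fatty acids, beta-oxidation, the cell wall and its integrity pathway, mating kinases, amino acid synthesis, proline and arginine breakdown, the proteasome, autophagy, the cell cycle, general stress and housekeeping. The list called glycolysis here also holds genes of gluconeogenesis, pyruvate decarboxylase and alcohol dehydrogenase. A further list, of mitochondrially encoded genes, matched 0 genes and was not tested. Names shared by unrelated proteins were corrected after the annotation was seen and before any test. Changes of lists are given relative to the median of all genes, except where stated. In differences between the species the median over all pairs is not taken off.

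Genes were named by a rule. It takes the 10 highest and 10 lowest called genes of each comparison with 0 min among those with a mean of at least 10 FPKM in the higher group, 4 members of smallest adjusted p in each list, a fixed set of osmotic stress genes, the pairs with the largest called species differences and the largest changes between successive harvests. The text draws from these and leaves many of them out. The metal uptake genes, HEM13 and the 30 min changes of ACS1 within each species and of MLS1 within H. pseudoburtonii stand outside the rule and were chosen after their values were seen. For the highest and lowest genes and the changes between successive harvests, the rule also asked that both later libraries lie on one side of both earlier ones. All 225 called changes of single genes that are printed had this, which the rule fixed in advance for the genes it took that way.

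The comparisons, tests, filter, lists and most alternatives were fixed before the data were examined. The alternatives were median-ratio and quantile scaling, pseudocounts of 0.1 and 10, no filter or a filter at 10 FPKM, no trend, a block for replicate number, at least 2-fold calls and each library left out in turn. A further 5, chosen after the data were seen, left out 2 libraries together, repeated the list tests between successive harvests without each library and under both scalings, took pairs with gene spans within 10 percent, tested lists on the species difference and summed copies of glycolysis enzymes.

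The tests were tried on simulated data with 200 changed genes in each species. Changed genes were drawn from those with a mean of at least 10 FPKM, and noise was independent between genes. Changes of log2 1, 2 and 3 were called for 55.4, 80.8 and 94.4 percent of genes in H. burtonii and 27.3, 82.1 and 94.9 percent in H. pseudoburtonii, with 9 of 166 and 12 of 156 calls falling on unchanged genes. Among 248 changed pairs, 26.9, 80.2 and 94.6 percent of those that differed by log2 1, 2 and 3 were called. Of 187 calls, 10 fell on unchanged pairs. A gene that is not called may therefore still have changed about 2-fold. Recovery of genes with a mean under 10 FPKM was not measured.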

Results

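RNA-seq libraries were made from wild-type cultures of the yeasts Hyphopichia burtonii (strain KJJ43) and Hyphopichia pseudoburtonii (strain KJS14), isolated from Nuruk, a Korean fermentation starter. Cultures were grown in YPD from an OD600 of 0.6 to 2.0, and an equal volume of YPD with 2 M NaCl was then added, giving 1 M NaCl. Cells were harvested before the addition (0 min) and 5, 15 and 30 min after it, with 2 libraries per species and time and 16 libraries in all. The later samples received fresh medium as well as salt and no course without salt is present, so an effect of salt and an effect of added medium cannot be told apart. The library numbers form 1 series for each species, so species and library series coincide. A shift shared by all libraries of a series cancels in changes from 0 min. Whether the 2 libraries of a time came from separate cultures is not given in the sources used here, and p-values measure the spread between these samples alone.

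The table of H. burtonii held FPKM for 6115 genes and that of H. pseudoburtonii for 5900, of which 5008 and 4834 carried a gene name, on 8 chromosomes each. FPKM summed to between 1259069 and 1498017 per library. Read counts were not given. Relative depth was roughly estimated from the lowest nonzero products of FPKM and gene span in each library. It differed more than 2-fold within H. burtonii (0.464 to 1) and within H. pseudoburtonii (0.267 to 1). Estimated depth went with time. By this estimate the 0 min libraries were the shallowest in H. burtonii (0.541 and 0.464, later ones 0.583 to 1). They were the deepest in H. pseudoburtonii (0.974 and 1, later ones 0.267 to 0.505). An effect of depth on low values would not cancel in changes from 0 min and was not tested. Replicates correlated across genes at r = 0.957, 0.990, 0.968 and 0.984 at 0, 5, 15 and 30 min in H. burtonii and at 0.979, 0.943, 0.924 and 0.959 in H. pseudoburtonii. Actin (ACT1) was not called at any time. Its log2 change was -0.31, -0.40 and -0.21 in H. burtonii and -0.03, -0.10 and -0.35 in H. pseudoburtonii, where quantile scaling turned the first 2 to 0.31 and 0.20 and leaving out 0 min replicate 2 the first to 0.04. With median-ratio scaling ACT1 was -0.77 and -0.72 and called lower in H. burtonii at 15 and 30 min, and -0.75 and called lower in H. pseudoburtonii at 30 min, where it was also called without either 15 min library. Gene IDs are reused between the species, and where a name occurs on several genes of a species the ID is given. How reads shared by close copies, overlapping genes or genes on opposite strands were divided is not given in the sources used here, so values of single copies of STL1, ENA5, GPD, ADH1 and HGT1 are uncertain.

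The comparison of 5 with 0 min asked which genes of H. burtonii respond first. RCN1, which encodes a calcipressin and is induced through calcineurin in other yeasts, went from 118 ± 26.8 to 801 ± 17.8 FPKM (SD, n = 2; log2 change 2.77, SE 0.19, adjusted p = 0.000327). The vacuolar calcium pump gene PMC1 rose by 2.88 (SE 0.23), the potassium transporter gene HAK1 by 2.80 (SE 0.27), and the sodium pump gene ENA5 (TBIG002789) by 2.32 (SE 0.29). As groups, calcineurin and calcium transport (3 higher and 1 lower of 12, the same adjusted over the list alone; camera adjusted p = 0.190) and sodium, potassium and proton transport (5 and 0 of 16, the same; adjusted p = 0.101) were not called. Cell wall synthesis had 10 genes higher and 6 lower of 42 (11 and 6 adjusted over the list alone) and was not called as a group either (adjusted p = 0.153). The mannosyltransferase gene MNT2 (TBIG002361, 3.37), the chitin synthase gene CHS2 (TBIG002305, 2.36) and KRE6 (TBIG004878, 2.09), needed for beta-1,6-glucan, were among the higher, and the wall integrity transcription factor gene RLM1 rose by 2.65. Of the genes that make glycerol, the main osmolyte of many yeasts, the glycerol phosphatase gene RHR2 (TBIG004428) rose by 1.68 (SE 0.15) and the glycerol-3-phosphate dehydrogenase gene GPD (TBIG000228) by 1.12 (SE 0.21), while the second phosphatase copy RHR2 (TBIG004344) was not called (0.11). Without 5 min replicate 1 or 2 that GPD change was 1.13 and 1.12 and no longer called, and HSP12 (1.10, SE 0.18) was 1.11 and 1.10 and no longer called. HOG1 (-0.09), NHA1 (-0.51), CTT1 (-0.38), TPS1 (1.10), TPS2 (0.46) and HSP104 (1.23) were not called, although TPS1 at 1.51 and HSP104 at 1.76 were called without 0 min replicate 2 and both without either 15 min library, with median-ratio scaling (1.07 and 1.20) and with a replicate block (1.10 and 1.23), TPS1 also with quantile scaling (1.13). PBS2 (1.29, SE 0.38) passed, but lost its call without any 0, 5 or 30 min library (1.19 to 1.39), with quantile scaling (0.92), with a pseudocount of 10 (0.51) and with a replicate block (1.29). Of the STL1 copies, of a family that imports glycerol in other yeasts, TBIG002605 lay at -2.25 (SE 0.25) and TBIG002607 at 2.50 (SE 0.58), while the most abundant, TBIG005317 (0.22), TBIG002606 (0.13) and TBIG005322 (0.13) were not called. The TBIG002607 call was lost without 0 min replicate 1 (1.78) or either 5 min library (2.68 and 2.31), and TBIG002606 turned to -0.36 without 5 min replicate 2. The phosphate transporter gene PHO84 (-4.94, SE 0.31) and the glycerophosphoinositol transporter gene GIT1 (-4.47, SE 0.27) were among the genes that fell furthest. The acetate-use genes ICL1 (-2.98) and MLS1 (-3.14) and the glycogen phosphorylase gene GPH1 (-2.32) fell too.

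In H. burtonii at 5 min, limma called 1348 of 6047 genes, 675 higher and 673 lower, with a median change of all genes of 0.07. Without 1 library the count was 879 (0 min replicate 1), 200 (5 min replicate 1) or 178 (5 min replicate 2). Ribosome biogenesis had the smallest adjusted p of the lists. Of its 131 measured genes 48 rose and 0 fell (59 and 0 adjusted over the list alone), with a median 0.93 above that of all genes (camera adjusted p = 4.36e-13, adjusted p = 0.524 with an estimated correlation). BFR2 (2.32, SE 0.24), NOP53 (2.88, SE 0.35) and RIX7 (TBIG000543, 1.67, SE 0.20), which act in small- or large-subunit assembly, were among them. Cytosolic ribosomal protein genes rose in 19 of 81 cases (20 adjusted over the list alone; adjusted p = 4.38e-07, 0.524 with an estimated correlation), chaperone genes in 12 of 27 (16; adjusted p = 4.59e-05, 0.524), translation factor and aminoacyl-tRNA synthetase genes in 14 of 50 (14; adjusted p = 0.0304, 0.524) and RNA polymerase I and III genes in 5 of 26 (5; adjusted p = 0.0138, 0.524), with 0 lower in each. Peroxisomal beta-oxidation fell, with 10 of 15 genes lower and 0 higher (11 adjusted over the list alone; median -1.16 from all genes; adjusted p = 1.40e-06, 0.524 with an estimated correlation), among them POX2 (-2.78, SE 0.22) and YAT1 (-1.66, SE 0.17). Amino acid biosynthesis fell in 23 of 80 genes and rose in 4 (27 and 5 adjusted over the list alone; adjusted p = 0.00137, 0.524), with LEU4 (TBIG002574, -1.85), PRO1 (-1.70) and trp4 (-1.46) lower.

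In H. burtonii at 15 min RHR2 (TBIG004344, chromosome 5, start 718819) had risen from 34.0 ± 1.12 to 1536 ± 283 FPKM (log2 change 5.45, SE 0.17, adjusted p = 3.70e-06), and GCY1 (TBIG001529), whose product can turn glycerol into dihydroxyacetone, by 6.77 (SE 0.28). GPD (TBIG000228, chromosome 1, start 455912) was 1.75 (SE 0.21) higher and the other RHR2 copy (TBIG004428) 1.54 (SE 0.15), while the other glycerol-3-phosphate dehydrogenase copy, GPD (TBIG005904), was not called (0.13) and turned to -0.11 without 0 min replicate 2 and just below 0 (-0.004) without 15 min replicate 1. Of the STL1 copies TBIG002606, TBIG002607 and TBIG005322 rose by 1.72 (SE 0.30), 2.39 (SE 0.58) and 0.79 (SE 0.16), TBIG002605 lay at -1.83 (SE 0.25) and TBIG005317 was not called (0.41). TBIG002607 lost its call without 0 min replicate 1 (1.67) or 15 min replicate 2 (1.67), and TBIG005322 with median-ratio scaling (0.43). The sodium pump gene ENA5 (TBIG002789) rose by 5.37 (SE 0.29), with its copies TBIG001727 and TBIG001730 at 3.03 and 2.54, the catalase gene CTT1 by 3.77 (SE 0.19), the sorbose reductase gene SOU2 by 4.45 (SE 0.27) and HSP12 by 1.84 (SE 0.18). An arabinose dehydrogenase and a transketolase gene were among the highest, ARA1 (TBIG002950) at 5.81 (SE 0.18) and TKT (TBIG005019) at 4.83 (SE 0.23). The wall gene KRE6 (TBIG004878) reached 3.37, and GAD1 (TBIG000839) and UGA1, of 4-aminobutyrate metabolism, 3.01 and 2.19. The antiporter gene NHA1 (0.74) and the kinase genes HOG1 (0.65) and PBS2 (1.52) of the osmotic stress pathway passed only narrowly. NHA1 lost its call whichever of the 8 libraries was left out, with values from 0.58 (without 15 min replicate 1) to 0.91 (without 15 min replicate 2), and was 0.39 and 0.28 under median-ratio and quantile scaling. HOG1 lost its call without 0 min replicate 1 (0.53), 15 min replicate 2 (0.51) or any 5 or 30 min library (0.65 each) and was 0.29 and 0.53 under those scalings, and PBS2 lost it without 15 min replicate 2 (0.96) and with quantile scaling (0.74). HSP104 was not called (0.30). The sterol demethylase gene ERG11 (TBIG005583) fell by 3.84 (SE 0.24), the copper transporter gene CTR1 fell by 4.52 (SE 0.28) and the general amino acid permease gene GAP1 (TBIG002356) fell by 3.57 (SE 0.34).

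At 15 min 1798 of the 6047 H. burtonii genes were called, 1379 higher and 419 lower, or 913 without 15 min replicate 2. The median of all genes was 0.39 above 0 min, and the split was 704 higher and 743 lower with median-ratio and 555 and 624 with quantile scaling. Relative to all genes the glycerol list lay 1.01 higher (11 of 15 higher, 1 lower; 12 and 1 adjusted over the list alone; camera adjusted p = 0.00207, adjusted p = 0.282 with an estimated correlation). Glycolysis lay -1.26 from all genes at the median (14 of 25 lower, 5 higher; the same numbers adjusted over the list alone; adjusted p = 3.0e-07, 0.198 with an estimated correlation), with ADH1 (TBIG002724) at -2.83 (SE 0.17) and TDH1 at -2.30 (SE 0.20), but ENO1 (TBIG003526) at 2.89 (SE 0.19) and PDC1 at 2.24 (SE 0.17) above 0 min. Ergosterol biosynthesis fell in 10 of 31 genes and rose in 1 (11 and 1 adjusted over the list alone; adjusted p = 9.81e-06, 0.228), including ERG1 (TBIG004941, -1.88). Sugar transporter genes fell in 5 of 14 and rose in 1 (6 and 2 adjusted over the list alone; adjusted p = 0.00108, 0.282). Ribosome biogenesis was higher in 55 of 131 genes with 0 lower (62 adjusted over the list alone; adjusted p = 0.000153, 0.630), or 32 and 21 higher with 1 lower each under median-ratio and quantile scaling. Cell wall genes rose in 20 of 42 and fell in 4 (22 and 4; adjusted p = 0.0464, 0.526), and proline and arginine catabolism rose in 7 of 12 with 0 lower (9 adjusted over the list alone; adjusted p = 0.00537, 0.282).

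The remaining lists called in H. burtonii at 15 min lay lower than all genes, apart from the proteasome. Amino acid biosynthesis had 16 of 80 genes lower and 8 higher (the same adjusted over the list alone; adjusted p = 0.000540, 0.282 with an estimated correlation), including ARO2 (-1.26) and ILV2 (-1.40), or 26 lower and 1 higher with median-ratio scaling. In the TCA cycle list MLS1 (-3.96, SE 0.34) alone of 21 genes fell (1 adjusted over the list alone; adjusted p = 0.00880, 0.282), and of the beta-oxidation genes 3 of 15 fell, POX2 at -2.30 (3; adjusted p = 0.00537, 0.315). Of 31 proteasome genes 8 rose, RPT5 among them (0.68), but 0 adjusted over the list alone (adjusted p = 0.0181, 0.526) and 0 under median-ratio or quantile scaling. RPT5 lost its call without 0 min replicate 1 (0.50), either 5 min library (0.68 each) or either 15 min library (0.68 and 0.67). The cell cycle and histone list had 2 genes higher and 1 lower of 32 (1 and 1 adjusted over the list alone) and a median of -0.51 from all genes (adjusted p = 0.0458, 0.533). Where the median of all genes (0.39) is not taken off, its median was -0.12 and its mean 0.06.

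At 30 min RHR2 (TBIG004344) of H. burtonii reached 7439 ± 444 FPKM (log2 change 7.73, SE 0.17, adjusted p = 4.97e-07), GCY1 (TBIG001529) was 7.51 (SE 0.28) higher, ENA5 (TBIG002789) 5.49 (SE 0.29) and CTT1 5.00 (SE 0.19), from 118 ± 12 to 3794 ± 246 FPKM. NHA1 rose by 1.84 (SE 0.21) and the kinase genes HOG1 and PBS2 by 0.99 (SE 0.17) and 2.09 (SE 0.38); HOG1 was 0.49 and not called with median-ratio scaling. PGA12 (TBIG003757, 7.73, SE 0.29), annotated as phosphomutase-like, ARA1 (TBIG002950, 7.38, SE 0.18) and TKT (TBIG005019, 6.63, SE 0.23) were among the genes that rose furthest. ADH1 (TBIG002724) fell by 5.17 (SE 0.17), ADH3 fell by 5.17 (SE 0.19), TDH1 fell by 4.72 (SE 0.20) and ERG11 (TBIG005583) fell by 6.57 (SE 0.24). The membrane heat shock gene HSP30 fell by 7.26 (SE 0.17), the nitric oxide dioxygenase gene YHB1 fell by 6.41 (SE 0.17) and the disaggregase gene HSP104 fell by 3.27 (SE 0.39). The glycerol transporter gene STL1 (TBIG002605) went from 250.3 ± 11.4 to 11.4 ± 3.32 FPKM (-4.37, SE 0.25) and its copy TBIG002606 lay at -1.32 (SE 0.30), while TBIG005317 (-0.19), TBIG005322 (-0.04) and TBIG002607 (-0.48) were not called. The TBIG002606 call was lost without 30 min replicate 1 (-1.31), TBIG005317 and TBIG005322 were called lower with median-ratio scaling (-0.70 and -0.55), and without 0 min replicate 2 TBIG002607 and TBIG005322 turned to 0.24 and 0.05. The adhesin gene ALS3 was listed at 0 in both 30 min libraries. TPS1, of trehalose synthesis, fell by 1.16 (SE 0.34) and was not called without 0 min replicate 2 (-0.75) or without either 30 min library (-1.07 and -1.25), and RCN1 was no longer called (0.46) except without 0 min replicate 2 (0.69). GPD (TBIG000228) was 1.33 (SE 0.21) and HSP12 1.69 (SE 0.18) above 0 min. A GPD copy annotated as glyceraldehyde-3-phosphate dehydrogenase (TBIG002932) was -0.65 (SE 0.21) from 0 min, lost its call without 0 min replicate 1 (-0.50), either 30 min library (-0.56 and -0.73) or either 5 min library (-0.65 each), and was 0.46 under quantile scaling.

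Of the 6047 genes 2907 were called at 30 min, 2236 higher and 671 lower, or 1785 and 1882 without 30 min replicate 1 and 2. The median of all genes was 0.56 above 0 min, and the split was 1022 higher and 1092 lower with median-ratio and 983 and 1012 with quantile scaling. Glycolysis lay -2.14 from all genes (-2.17 and -1.93 under those scalings), with 18 of 25 genes lower and 4 higher, the same adjusted over the list alone (camera adjusted p = 1.73e-10, adjusted p = 0.101 with an estimated correlation). Sugar transporter genes lay -1.55 from all genes with 10 of 14 lower and 2 higher (the same adjusted over the list alone; adjusted p = 3.12e-06, 0.145), HGT1 (TBIG006104) at -5.69 (SE 0.19) and HXT7 at -3.23 (SE 0.23). Chaperone genes, higher at 5 min, were lower in 13 of 27 cases and higher in 3 (13 and 4 adjusted over the list alone; median -1.07 from all genes; adjusted p = 3.12e-06, 0.471), with HSP78 (TBIG002281) at -2.34 (SE 0.16) and SIS1 at -1.60 (SE 0.16). Ergosterol biosynthesis had 9 of 31 lower and 2 higher (the same adjusted over the list alone; adjusted p = 0.000140, 0.248), ERG25 (TBIG004685) at -4.03 (SE 0.20). Proteasome genes rose in 25 of 31 cases with 0 lower (28 adjusted over the list alone; adjusted p = 0.000778, 0.641), RPT5 by 1.45 and RPN1 by 1.19, or in 6 and 17 under median-ratio and quantile scaling. The glycerol list was not called as a group (7 of 15 higher, 3 lower, the same adjusted over the list alone; adjusted p = 0.999), with a log2 median of -0.04 and a mean of 1.08 where the median of all genes is not taken off, and genes of the Hog1 pathway rose in 11 of 16 and fell in 1 (12 and 1; adjusted p = 0.258), or rose in 3 and fell in 1 with median-ratio scaling. Amino acid biosynthesis, lower at 5 and 15 min, had 40 of 80 genes higher and 6 lower (the same adjusted over the list alone) at a median 0.27 above all genes and was not called (adjusted p = 0.212), with 24 higher and 14 lower under median-ratio scaling. Trehalose and glycogen genes fell in 3 of 12 with 0 higher (3; adjusted p = 0.0484, 0.641). Beta-oxidation fell in 3 of 15 and rose in 2 (the same adjusted over the list alone; adjusted p = 0.0484, 0.641), POX2 at -3.33 (SE 0.22), at a median of -0.54 from all genes. Where the median of all genes is not taken off, the median was 0.02 and the mean -0.38. Under the other scalings 7 and 4 were lower with 0 higher.

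**Figure D1:**
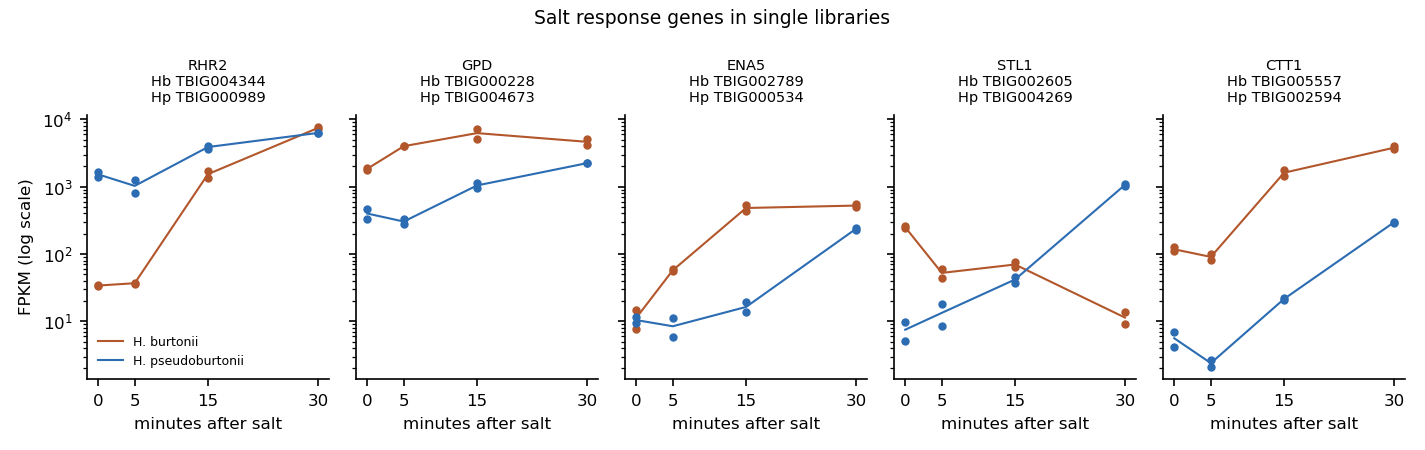
FPKM on a log scale in each library (points) and their means (lines) for 1 copy each of RHR2, GPD, ENA5, STL1 and CTT1 in both species, against minutes after salt was added. RHR2 of H. burtonii rose from 34.0 to 7439 FPKM and STL1 of H. pseudoburtonii from 7.52 to 1064 FPKM, while the plotted STL1 copy of H. burtonii fell by 4.37 in log2. Its most abundant copy (TBIG005317), not plotted, went from 1432 to 1254 FPKM and was not called. The plotted copies of RHR2, GPD, ENA5 and STL1 were not matched as counterparts between the species. A second RHR2 copy of H. pseudoburtonii (TBIG003552), not plotted, went from 11.5 to 53.7 FPKM and was not called.

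The same question was asked for H. pseudoburtonii at 5 min. TDH1 (TBIG004457), of glycolysis, fell by 6.20 (SE 0.30, adjusted p = 4.81e-05), from 4276 ± 264 to 58.7 ± 19.7 FPKM, the alcohol dehydrogenase genes ADH1 (TBIG000796 and TBIG003830) lay at -4.83 (SE 0.23) and -4.04 (SE 0.15), the pyruvate decarboxylase gene PDC11 fell by 3.41 (SE 0.23) and the hexose transporter gene HXT6 fell by 2.75 (SE 0.13). The sterol regulator gene sre1 (TBIG001775) fell by 6.19 (SE 0.24), the methylsterol monooxygenase gene ERG25 (TBIG004436) fell by 5.01 (SE 0.60), ERG11 (TBIG001777) fell by 4.62 (SE 0.52) and the alternative oxidase gene STO1 (TBIG005381) fell by 5.74 (SE 0.44). TPS1 (-1.21, SE 0.20) and TPS2 (-1.47, SE 0.22) of trehalose synthesis and HSP104 (-2.11, SE 0.31) fell, though without 0 min replicate 1 or 2 none was called, at -1.12 and -1.31 for TPS1, -1.45 and -1.50 for TPS2 and -2.0 and -2.22 for HSP104. The cyclin gene PCL1 rose by 2.11 (SE 0.30), the repressor gene YOX1 by 3.0 (SE 0.42) and the cohesin gene rad21 by 2.68 (SE 0.30), as did the proline permease gene put4 (TBIG001250, 2.57, SE 0.41), which lost its call without either 0 min library (2.32 and 2.83) or 5 min replicate 2 (2.62). None of GPD (TBIG004673, -0.38), RHR2 (TBIG000989, -0.60), STL1 (TBIG004269, 0.72), ENA5 (TBIG000534, -0.33), NHA1 (0.96), CTT1 (-0.93), RCN1 (-0.54), HOG1 (-0.47) and HSP12 (0.16) was called. Without 5 min replicate 2, RHR2 was -0.93 and called and HSP12 turned to -0.26, and without 5 min replicate 1 ENA5 turned to 0.09. PBS2 (-1.11) was called without 5 min replicate 1 (-1.53) and under median-ratio and quantile scaling (-1.23 and -1.11).

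At 5 min 506 of 5798 H. pseudoburtonii genes were called, 242 higher and 264 lower, with a median change of all genes of 0.12 and a split of 156 and 334 under median-ratio scaling. The count was 100 and 101 without 0 min replicate 1 and 2, 267 without 5 min replicate 2, and 283 and 287 without 30 min replicate 1 and 2. Glycolysis fell in 17 of 22 genes with 0 higher (17 adjusted over the list alone; median -1.36 from all genes; camera adjusted p = 3.73e-19, adjusted p = 0.193 with an estimated correlation). Ribosome biogenesis rose in 21 of 128 genes with 0 lower (49 adjusted over the list alone; median 0.48 above all genes; adjusted p = 1.37e-13, 0.193), or in 9 and 12 under median-ratio and quantile scaling. NOP58 (0.98, SE 0.16) had the smallest adjusted p in the list and was not called without 0 min replicate 1 or 2 (0.97 and 0.98). Translation factors and aminoacyl-tRNA synthetases rose in 4 of 46 with 0 lower (8 adjusted over the list alone; adjusted p = 0.000273, 0.193), with ALA1 at 1.18 (SE 0.20), whose call was lost without either 0 min library (1.13 and 1.24) or 5 min replicate 1 (1.11). Cytosolic ribosomal protein genes gave 0 of 83 calls. The histone H3 genes HHT2 (TBIG004060 and TBIG003480) lay at -1.26 (SE 0.14) and -0.95 (SE 0.12) within a cell cycle list of 9 higher and 4 lower genes of 29 (12 and 7 adjusted over the list alone) that was not called as a group (adjusted p = 0.221). The call of TBIG003480 was lost without either 0 min library (-0.97 and -0.92).

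At 15 min STL1 (TBIG001057) of H. pseudoburtonii, which imports glycerol in other yeasts, rose by 2.67 (SE 0.32, adjusted p = 0.00199) and its copy TBIG004272 by 1.19 (SE 0.16), GPD (TBIG004673) by 1.40 (SE 0.20) and RHR2 (TBIG000989) by 1.35 (SE 0.22). The other glycerol-3-phosphate dehydrogenase copy, GPD (TBIG002496), fell by 0.69 (SE 0.17), a call lost without any 1 of 6 libraries (-0.74 and -0.64 without 0 min replicate 1 and 2, -0.67 and -0.71 without 15 min replicate 1 and 2, -0.69 without either 30 min library). ENA5 (TBIG000206) rose by 1.47 (SE 0.26), NHA1 by 1.38 (SE 0.31) and CTT1 by 1.8 (SE 0.31). Of these, RHR2, ENA5, NHA1 and CTT1 each lost the call without at least 1 of the 0 min libraries, RHR2 at 1.23 without replicate 2, ENA5 at 1.55 and 1.39 and NHA1 at 1.34 and 1.42 without replicates 1 and 2 (and 1.09 without 15 min replicate 1), and CTT1 at 1.49 without replicate 1. The other sodium pump copy, ENA5 (TBIG000534), was not called (0.59), and the sodium, potassium and proton transport list, with 3 higher and 1 lower of 15 (the same adjusted over the list alone), was not called as a group (adjusted p = 0.288). The amino acid permease gene mtr rose by 5.82 (SE 0.55), the haem oxygenase gene HMX1 by 4.94 (SE 0.28), ARA1 (TBIG005734) by 3.98 (SE 0.41), the arabinitol dehydrogenase gene ARDH by 2.26 (SE 0.15) and the chaperone gene YDJ1 (TBIG004560) by 3.39 (SE 0.21). The lactate permease gene JEN1 and ICL1 were listed at 0 in both 0 min libraries, and the pump assembly gene VMA21 at 0 in both 15 min libraries. The log2 change of VMA21 had a wide SE (1.79), and 15 min replicate 1 had the lowest estimated depth of the species (0.267). Absence of the VMA21 transcript is therefore not shown. STL1 (TBIG004269) was 2.39 (SE 0.40) above 0 min and lost its call without 0 min replicate 2 (1.96). TDH1 (TBIG004457) was still -5.32 (SE 0.30) from 0 min and YHB1 (TBIG001196) -4.64 (SE 0.25), while TPS1 (-0.90, SE 0.20) fell but lost its call without either 0 min library (-0.80 and -1.0) or without 15 min replicate 1 (-0.87). TPS2 (-1.13, SE 0.22) lost it without either 0 min library (-1.11 and -1.15). HOG1 (-0.31), RCN1 (0.61), HSP12 (0.68) and PBS2 (-0.36) were not called, although HSP12 was called with quantile scaling (0.92).

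The test called 1026 of 5798 genes at 15 min, 574 higher and 452 lower, with a median of all genes of 0.11. Without 0 min replicate 1 and 2 it called 302 and 272, and without 15 min replicate 1 645. The split was 468 higher and 556 lower with median-ratio scaling. Glycolysis fell in 14 of 22 genes and rose in 1 (the same adjusted over the list alone; median -1.10 from all genes, -0.74 with quantile scaling; camera adjusted p = 8.39e-10, adjusted p = 0.658 with an estimated correlation), with PDC11 at -3.48 (SE 0.23) and ADH1 (TBIG000796) at -4.43 (SE 0.23). Ribosome biogenesis rose in 16 of 128 with 0 lower (11 adjusted over the list alone; adjusted p = 0.0369, 0.828), BMS1 at 0.89 (SE 0.18), which lost its call without either 0 min library (0.83 and 0.94) or 15 min replicate 1 (0.76). Ergosterol biosynthesis fell in 5 of 27 with 0 higher (5 adjusted over the list alone; adjusted p = 0.0221, 0.658), ERG25 (TBIG004436) at -4.73 (SE 0.60), or -3.61 and -5.85 without 15 min replicate 1 and 2, and ERG11 (TBIG001777) at -4.34 (SE 0.52). Glycerol genes rose in 6 of 15 and fell in 1 (7 and 1 adjusted over the list alone), a list not called as a group (adjusted p = 0.108). In amino acid biosynthesis 17 of 73 rose and 4 fell, LYS1 (TBIG002461) by 2.16 (SE 0.21) and ILV5 by 1.24 (SE 0.13), without a call for the list (adjusted p = 0.537).

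At 30 min STL1 (TBIG004269, chromosome 5, start 1597388) of H. pseudoburtonii rose from 7.52 ± 3.42 to 1064 ± 67.5 FPKM (log2 change 7.03, SE 0.40, adjusted p = 5.87e-05), STL1 (TBIG001057) by 4.62 (SE 0.32), STL1 (TBIG004272) by 2.80 (SE 0.16) and STL1 (TBIG000904) by 2.1 (SE 0.55), while STL1 (TBIG000905) was not called (1.87). The TBIG000904 call was lost without any 1 of the 0 and 30 min libraries (1.96 to 2.24) and with quantile scaling (1.25), and TBIG000905 was called without a filter, without a trend and with 5 min replicate 2 and 15 min replicate 1 left out together (1.87 each). The glycerol kinase gene GUT1 rose by 2.88 (SE 0.20), GPD (TBIG004673) by 2.50 (SE 0.20) and RHR2 (TBIG000989) by 2.05 (SE 0.22). CTT1 went from 5.60 ± 1.99 to 296 ± 6.86 FPKM (5.52, SE 0.31). ENA5 rose by 4.38 (SE 0.35) for TBIG000534 and 3.05 (SE 0.26) for TBIG000206, NHA1 by 2.13 (SE 0.31) and the phosphatase genes PTP3 and PTP2, which act on the Hog1 kinase, by 3.11 (SE 0.35) and 1.97 (SE 0.23). HSP12 (1.35, SE 0.30), HOG1 (1.19, SE 0.30) and RCN1 (1.11, SE 0.28) were called narrowly. Without 0 min replicate 1 and 2 they were 1.30 and 1.41, 1.16 and 1.22, and 1.00 and 1.23, and not called. Without 30 min replicate 1 and 2 HOG1 was 1.34 and 1.04 and not called, and HSP12 was 1.23 without replicate 1 and RCN1 0.72 without replicate 2. With median-ratio scaling all 3 also lost the call (0.95, 0.79 and 0.71), and RCN1 with quantile scaling (0.80). Among the other genes that rose furthest were araE (TBIG002147), by 6.41 (SE 0.38), the drug pump gene FLR1 by 5.93 (SE 0.31), ARA1 (TBIG005734) by 6.39 (SE 0.41), mtr by 6.35 (SE 0.55) and HMX1 by 5.89 (SE 0.28). TDH1 (TBIG004457) remained -4.80 (SE 0.30), PDC11 -3.90 (SE 0.23), the glycolysis regulator TYE7 -3.51 (SE 0.31) and ERG11 (TBIG001777) -4.03 (SE 0.52) from 0 min.

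Of the 5798 genes 2055 were called, 1493 higher and 562 lower, or 918, 943, 1109 and 1036 without 0 min replicate 1, 0 min replicate 2, 30 min replicate 1 and 30 min replicate 2. The median of all genes was 0.39 above 0 min, and the split was 883 higher and 989 lower with median-ratio and 833 and 868 with quantile scaling. The glycerol list rose in 11 of 15 genes with 0 lower (13 adjusted over the list alone; median 1.71 above all genes; camera adjusted p = 3.95e-05, adjusted p = 0.172 with an estimated correlation), and genes of the Hog1 pathway in 10 of 19 with 0 lower (10; adjusted p = 0.0415, 0.340). Beta-oxidation rose in 9 of 13 with 0 lower (11 adjusted over the list alone; adjusted p = 0.000713, 0.172), POX1 (TBIG000773) by 3.16 (SE 0.20) and SPS19 (TBIG003864) by 3.02 (SE 0.40). Cytosolic ribosomal protein genes fell in 50 of 83 with 0 higher (59 adjusted over the list alone; median -1.03 from all genes; adjusted p = 5.89e-26, 0.172), RPL8B (TBIG002329) at -2.00 (SE 0.14) and RPS9B at -1.52 (SE 0.13). With median-ratio scaling 72 were lower and 0 higher, but with quantile scaling 19 were lower and 7 higher at a median of -0.09 from all genes. Ribosome biogenesis fell in 29 of 128 and rose in 3 (26 and 2 adjusted over the list alone; adjusted p = 3.14e-08, 0.20), HAS1 (-1.53, SE 0.20) and NSA2 (-1.49, SE 0.21) lower. Translation factors fell in 9 of 46 and rose in 2 (9 and 1 adjusted over the list alone; adjusted p = 5.39e-05, 0.172), DED81 at -1.25 (SE 0.16). Glycolysis had 11 of 22 lower and 3 higher (11 and 5; adjusted p = 5.39e-05, 0.340), at a median of -0.94 from all genes but -0.26 with quantile scaling. With copies summed, 12 of 15 enzymes lay lower than all genes, while phosphoenolpyruvate carboxykinase, of gluconeogenesis, was 2.80 above 0 min.

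Further lists were called in H. pseudoburtonii at 30 min. Ergosterol biosynthesis fell in 7 of 27 genes and rose in 2 (the same adjusted over the list alone; camera adjusted p = 0.000713, adjusted p = 0.172 with an estimated correlation), ERG4 at -1.13 (SE 0.19). Respiratory chain genes fell in 7 of 31 with 0 higher (1 adjusted over the list alone; adjusted p = 0.000790, 0.340), or in 6 with 3 higher under quantile scaling. Proteasome genes rose in 12 of 30 with 0 lower (13 adjusted over the list alone; adjusted p = 0.0357, 0.20), RPT6 by 1.14 (SE 0.16), or in 2 with 1 lower under median-ratio scaling. RNA polymerase I and III genes fell in 5 of 28 and rose in 3 (3 and 2; adjusted p = 0.0357, 0.345), RPC40 at -0.99 (SE 0.20), a call lost without 0 min replicate 1 (-0.89) or 30 min replicate 2 (-0.87). Chaperone genes fell in 9 of 29 and rose in 6 (10 and 7; adjusted p = 0.0357, 0.536), with hsp10 at -2.09 (SE 0.25) and YDJ1 (TBIG004560) at 2.91 (SE 0.21). Their median lay -0.64 from all genes, 0.07 above them with quantile scaling. Their mean was 0.13 where the median of all genes is not taken off.

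Lists that were not called as groups against 0 min at any time still held called genes, and each is given at 30 min. Over all genes, 2236 were higher and 671 lower of 6047 in H. burtonii at that time. In H. pseudoburtonii these were 1493 and 562 of 5798. A list count near or under those shares marks no response of its own. Sodium, potassium and proton transport had 7 genes higher and 1 lower of 16 in H. burtonii (the same adjusted over the list alone; camera adjusted p = 0.262) and 6 and 1 of 15 in H. pseudoburtonii (the same; adjusted p = 0.0846). Sugar alcohol metabolism had 3 higher and 2 lower of 8 (4 and 3 adjusted over the list alone; adjusted p = 0.936) and 4 and 0 of 7 (the same; adjusted p = 0.0846). SOU2 rose by 4.93 (SE 0.27) in H. burtonii and by 3.43 (SE 0.32) in H. pseudoburtonii, and ARDH by 2.26 and 3.74. Calcineurin and calcium transport had 6 higher and 1 lower of 12 (7 and 1; adjusted p = 0.368) and 3 and 2 of 10 (4 and 2; adjusted p = 0.738), with PMC1 at 1.65 and 2.03. Oxidative stress defence had 8 higher and 6 lower of 26 (the same; adjusted p = 0.357) and 8 and 2 of 25 (9 and 2; adjusted p = 0.40), with PRX1 (TBIG000873) of H. burtonii at -1.77 and SOD6 of H. pseudoburtonii at 2.99. General stress genes had 10 higher and 5 lower of 26 (10 and 6; adjusted p = 0.999) and 10 and 1 of 23 (the same; adjusted p = 0.146), with PIR3 at 3.84 in H. burtonii. Autophagy had 8 higher and 4 lower of 31 (8 and 3; adjusted p = 0.999) and 11 and 0 of 29 (the same; adjusted p = 0.0798), with ATG8 at 2.53 and 4.07. Median-ratio scaling turned the balance of H. burtonii to 5 higher and 9 lower for oxidative stress, 7 and 8 for general stress and 2 and 6 for autophagy, and that of H. pseudoburtonii to 4 and 5 for oxidative stress and 1 and 2 for calcineurin.

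Fatty acid and sphingolipid synthesis had 8 genes higher and 5 lower of 19 in H. burtonii at 30 min (9 and 5 adjusted over the list alone; adjusted p = 0.368) and 2 and 3 of 18 in H. pseudoburtonii (1 and 2; adjusted p = 0.248), with SCS7 lower in both (-1.84 and -2.89). The mating and filamentation kinase list had 3 higher and 2 lower of 15 (2 and 2; adjusted p = 0.792) and 4 and 0 of 10 (5 and 0; adjusted p = 0.156), with CEK1 at 1.99 and CAG1 at 2.81. Cell wall integrity had 2 higher and 0 lower of 8 (the same; adjusted p = 0.999) and 1 and 1 of 7 (the same; adjusted p = 0.564), with RLM1 at 2.30 in H. burtonii. The pentose phosphate pathway had 3 higher and 0 lower of 5 in H. burtonii (the same; adjusted p = 0.258), SOL3 at 2.00, and 0 of 4 called in H. pseudoburtonii, too few members for a list test. Housekeeping genes had 4 higher and 1 lower of 9 (the same; adjusted p = 0.999) and 2 and 1 of 9 (the same; adjusted p = 0.564), with the TATA-binding protein gene higher in both (tbp1 1.29, SPT15 1.28). With median-ratio scaling fatty acid synthesis of H. burtonii turned to 2 higher and 6 lower and the housekeeping genes to 1 and 2 in H. burtonii and 1 and 3 in H. pseudoburtonii.

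**Figure D2:**
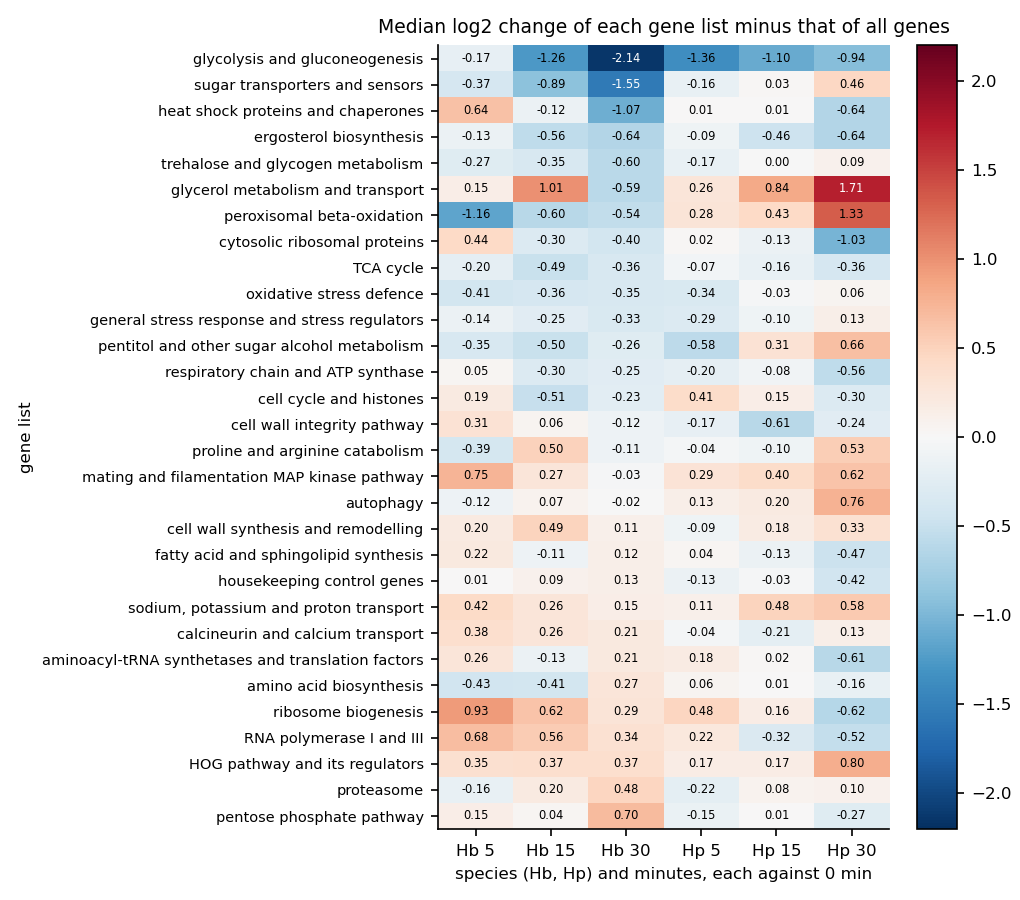
Median log2 change of each gene list minus that of all genes, for both species at 5, 15 and 30 min against 0 min, in FPKM as deposited (colour and number in each cell). Glycolysis reached -2.14 in H. burtonii at 30 min, and the chaperone value of -0.64 in H. pseudoburtonii at 30 min turned to 0.07 with quantile scaling.

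Comparisons of successive harvests, all after the medium was added, asked which genes went on moving. In H. burtonii GCY1 (TBIG001529) rose by 6.52 (SE 0.28) between 5 and 15 min, RHR2 (TBIG004344) by 5.33 (SE 0.17) and PGA12 (TBIG003757) by 5.01 (SE 0.29), while CTR1 fell by 3.11 (SE 0.28) and the iron permease gene FTR1 (TBIG001982) fell by 2.73 (SE 0.34). Between 15 and 30 min HSP30 (-4.90, SE 0.17), YHB1 (-4.15, SE 0.17), HGT1 (TBIG006104, -4.08, SE 0.19) and HSP104 (-3.58, SE 0.39) fell, and the amino acid genes HOM3 (2.82, SE 0.22) and BAT2 (TBIG000558, 2.80, SE 0.28) rose. In H. pseudoburtonii mtr rose by 3.19 (SE 0.55) between 5 and 15 min, and STL1 (TBIG004269) by 4.64 (SE 0.40) and FLR1 by 4.51 (SE 0.31) between 15 and 30 min, when the ribosome biogenesis gene NSA2 fell by 2.08 (SE 0.21). The mtr call was lost without 5 min replicate 2 (2.97), either 15 min library (3.33 and 3.06) or either 30 min library (3.19 in both), with a pseudocount of 0.1 (3.30) and without a trend (3.19).

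As groups, in tests that were not planned beforehand, 13 lists were called in H. burtonii between 5 and 15 min and 7 between 15 and 30 min, and 0 in either comparison with an estimated correlation. From 5 to 15 min chaperone genes had 8 of 27 lower and 2 higher (9 and 2 adjusted over the list alone; camera adjusted p = 4.65e-08, adjusted p = 0.249 with an estimated correlation), glycolysis 13 of 25 lower and 5 higher (14 and 6; adjusted p = 2.94e-07, 0.223) and ergosterol biosynthesis 7 of 31 lower and 0 higher (8; adjusted p = 4.65e-06, 0.226). Ribosomal protein genes lay -0.81 from all genes (adjusted p = 5.62e-17, 0.229) with 8 of 81 lower and 1 higher, but 0 adjusted over the list alone, and -0.26 with 0 called under quantile scaling. Higher as groups were the proteasome, proline and arginine catabolism, beta-oxidation and glycerol lists, with 14 of 31, 8 of 12, 8 of 15 and 7 of 15 genes higher and 0 lower in each (18, 10, 10 and 8 adjusted over the list alone), or 5, 5, 2 and 6 under median-ratio scaling (adjusted p = 0.359, 0.229, 0.359 and 0.359 with an estimated correlation). The other 5, translation factors, ribosome biogenesis, cell cycle, respiration and fatty acid synthesis, lay lower than all genes with at most 5 genes called lower (0.664 for ribosome biogenesis and 0.359 for each other list with an estimated correlation). Without 5 min replicate 1 the counts fell to 1 lower chaperone, 4 glycolysis, 1 ergosterol and 0 ribosomal protein genes, and to 0 higher proteasome, 3 proline and arginine, 1 beta-oxidation and 3 glycerol genes, although the groups were still called, and lower ribosome biogenesis genes were 19 without 15 min replicate 2. Group calls were lost for ribosome biogenesis (adjusted p = 0.424), respiration (0.157) and fatty acid synthesis (0.166) without 15 min replicate 1, for respiration without 5 min replicate 2 (0.134) and for fatty acid synthesis without 0 min replicate 1 (0.0503). Fatty acid synthesis also lost it with median-ratio (0.0593) and quantile scaling (0.0872), and respiration with quantile scaling (0.544). From 15 to 30 min amino acid biosynthesis had 36 of 80 higher and 1 lower (39 and 4; median 0.60 above all genes; adjusted p = 2.83e-08, 0.158), chaperone genes 13 of 27 lower and 1 higher (14 and 1; adjusted p = 2.83e-08, 0.294) and glycolysis 11 of 25 lower and 3 higher (15 and 4; adjusted p = 3.64e-07, 0.158). Sugar transporters (6 of 14 lower, 0 higher) and ribosome biogenesis (7 of 131 lower, 2 higher) lay lower too, and translation factors (15 of 50) and the proteasome (8 of 31) higher, the last with 1 higher under median-ratio scaling (adjusted p = 0.253, 0.855, 0.643 and 0.664 in that order with an estimated correlation). Without 30 min replicate 1 the higher amino acid genes fell to 15, translation factors to 2 and proteasome genes to 0, and lower ribosome biogenesis genes to 2, against 14 without 15 min replicate 1. Lower sugar transporter genes fell to 4 without 15 min replicate 2 or either 30 min library. The group call of the proteasome was lost without 15 min replicate 1 (adjusted p = 0.174), and that of ribosome biogenesis without 15 min replicate 2 (0.679) or 30 min replicate 2 (0.0580). The glycerol list had 1 gene higher and 6 lower of 15 (4 and 6 adjusted over the list alone), at a median of -0.43 from all genes, and was not called (adjusted p = 0.0648).

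In H. pseudoburtonii 12 lists were called between 5 and 15 min and 9 between 15 and 30 min, or 0 and 1 with an estimated correlation. From 5 to 15 min no list had more than 7 called genes. Ribosome biogenesis had 7 of 128 lower (10 adjusted over the list alone; adjusted p = 1.26e-05, 0.324 with an estimated correlation), and glycolysis 3 of 22 higher (9; adjusted p = 0.000321, 0.324) and glycerol 4 of 15 higher (5; adjusted p = 0.0101, 0.324), with 0 the other way in each. The proteasome, oxidative stress, Hog1 pathway, sugar alcohol and trehalose lists lay higher than all genes and ribosomal proteins, translation factors, RNA polymerases and ergosterol lower, with 3 or fewer called genes in each (adjusted p = 0.475 for ribosomal proteins and 0.324 for each other list with an estimated correlation). Without 5 min replicate 1 only 4 lists were called, and the call of glycolysis was lost (adjusted p = 0.0971) with those of the proteasome (0.144), oxidative stress (0.283), Hog1 pathway (0.0830), sugar alcohols (0.151), trehalose (0.252), RNA polymerases (0.119) and ergosterol (0.0830). Without 15 min replicate 2 translation factors (0.121), sugar alcohols (0.121) and oxidative stress (0.104) lost theirs, without 15 min replicate 1 ribosomal proteins (0.0864), the Hog1 pathway (0.235) and trehalose (0.268), and ribosomal proteins also without 5 min replicate 2 (0.0581). Trehalose and ergosterol lost the call without most single libraries, and the 7 lower ribosome biogenesis genes were 0 without either 0 min library. Sugar alcohols, trehalose and ergosterol also lost the call with median-ratio (0.0534 each) and quantile scaling (0.0603, 0.0822 and 0.0812), and ribosomal proteins with quantile scaling (0.153). From 15 to 30 min ribosomal protein genes had 43 of 83 lower and 0 higher (57 adjusted over the list alone; adjusted p = 1.66e-38, 0.112), or 18 lower and 1 higher with quantile scaling, ribosome biogenesis 40 of 128 lower and 0 higher (52; adjusted p = 6.89e-29, 0.0759) and translation factors 7 of 46 lower and 0 higher (13; adjusted p = 5.78e-13), the last called with an estimated correlation as well (adjusted p = 0.0239). The glycerol list had 9 of 15 higher and 0 lower (11; median 1.18 above all genes; adjusted p = 4.98e-06, 0.0981). Chaperone (5 of 29 lower, 1 higher) and respiration genes (3 of 31 lower) lay lower, and beta-oxidation (3 of 13 higher), sugar alcohol (5 of 7) and general stress genes (8 of 23) higher (adjusted p = 0.338, 0.335, 0.210, 0.335 and 0.199 in that order with an estimated correlation). Without 30 min replicate 2 the counts were 0 lower ribosomal protein, 1 ribosome biogenesis, 0 translation factor and 0 chaperone genes and 2 higher glycerol genes, and without 30 min replicate 1 they were 1, 1, 0, 0 and 3, although these groups were still called. Sugar alcohols lost the group call without 30 min replicate 1 (adjusted p = 0.0557) and general stress without 15 min replicate 2 (0.0935) or 30 min replicate 1 (0.0737).

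H. burtonii had 1214 called genes between 5 and 15 min, 975 higher and 239 lower, with a median of all genes of 0.32. The split was 274 higher and 399 lower with median-ratio scaling and 336 and 362 with quantile scaling. The count was 120 and 151 without 5 min replicate 1 and 2, 320 without 15 min replicate 1, and 726 and 728 without 30 min replicate 1 and 2. From 15 to 30 min 981 genes were called, 574 higher and 407 lower (284 and 483 with median-ratio, 368 and 493 with quantile scaling; median of all genes 0.13). That count was 520 and 524 without 5 min replicate 1 and 2, 444 without 15 min replicate 2, and 240 and 348 without 30 min replicate 1 and 2. H. pseudoburtonii had 277 called genes between 5 and 15 min, 177 higher and 100 lower, against 93 and 91 without 0 min replicate 1 and 2, 102 without 5 min replicate 2, 171 without 15 min replicate 1, and 98 and 96 without 30 min replicate 1 and 2. From 15 to 30 min 831 genes were called, 635 higher and 196 lower (335 and 414 with median-ratio, 342 and 410 with quantile scaling; median of all genes 0.34). That count was 286 and 291 without 0 min replicate 1 and 2, 373 without 15 min replicate 1, and 28 and 22 without 30 min replicate 1 and 2.

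Whether the species differed was tested on 3399 gene pairs as the change in H. pseudoburtonii minus that in H. burtonii. MLS1, of the glyoxylate cycle, differed by 3.88 (SE 0.41) at 15 min and 6.61 (SE 0.41, adjusted p = 5.98e-07) at 30 min, when it was -5.27 in H. burtonii and 1.34 in H. pseudoburtonii. ICL1, which acts just before it, differed at all 3 times. It was listed at 0 in both 0 min libraries of H. pseudoburtonii and at 211 ± 52.1 FPKM at 30 min, against 1326 ± 144 and 1060 ± 122 FPKM in H. burtonii. The acetyl-CoA synthetase gene ACS1 differed by 8.22 (SE 0.39), at -4.74 in H. burtonii and 3.48 in H. pseudoburtonii. HSP30 (8.57, SE 1.34), TMA10 (8.67, SE 0.55), HMX1 (8.26, SE 0.50) and the proline permease gene put4 (TBIG001334 and TBIG001250, 8.37, SE 0.62) differed in the same direction at 30 min. At 5 min sre1 (TBIG005586 and TBIG001775) differed by -6.60 (SE 0.30), the alternative oxidase gene STO1 at -6.77 (SE 0.53), TYE7 at -6.50 (SE 0.69), ERG25 (TBIG004685 and TBIG004436) at -5.50 (SE 0.69) and RGI1 at -6.81 (SE 1.42), each lower in H. pseudoburtonii, and RGI1 lost its call with a pseudocount of 0.1 (-8.60) and was -8.01 and -5.61 without 5 min replicate 1 and 2 of H. pseudoburtonii. The lists of these pathways were not called at 5 min, with a median difference of -0.02 for ergosterol biosynthesis (7 of 18 pairs called, camera adjusted p = 0.706) and -0.25 for the respiratory chain (1 of 26, adjusted p = 0.692). At 15 min STO1 (TBIG000146 and TBIG005381, -4.62, SE 0.53) and the magnesium transporter gene ALR2 (-5.40, SE 1.13) lay lower there, and CTR3 (4.78, SE 1.17) higher. ALR2 was -3.53 and -7.28 without 15 min replicate 1 and 2 of H. pseudoburtonii. CTR3 was 6.07 and 3.48 without 0 min replicate 1 and 2 of H. burtonii and was not called without 0 min replicate 1 (4.47) or 15 min replicate 1 (3.82) of H. pseudoburtonii. The ribosome assembly gene NIP7 differed by -4.44 (SE 0.69) and the tRNA exporter gene LOS1 differed by -4.54 (SE 0.52) at 30 min, higher in H. burtonii and lower in H. pseudoburtonii.

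The difference was called for 528 pairs at 5 min (267 higher and 261 lower in H. pseudoburtonii), 707 at 15 min (200 and 507) and 1227 at 30 min (436 and 791), around median differences over all pairs of 0.05, -0.33 and -0.28. At 5 min the split was 210 and 327 with median-ratio scaling, and the count was 281 and 247 without H. burtonii 5 min replicate 1 and 2 and 276 and 298 without H. pseudoburtonii 0 min replicate 1 and 2. At 15 min the split was 300 and 369 with median-ratio and 296 and 296 with quantile scaling, and the count was 453 without H. burtonii 15 min replicate 2 and 407 and 413 without H. pseudoburtonii 0 min replicate 1 and 2. Across gene pairs, which are not independent replicates, the changes of the species correlated at r = 0.02, 0.13 and 0.07 at 5, 15 and 30 min (Spearman's rho 0.04, 0.11 and 0.02). At 5 min r was -0.02 and 0.06 without H. pseudoburtonii 5 min replicate 1 and 2, and at 30 min it was 0.03 without H. burtonii 0 min replicate 1. At 5 min 105 pairs were called in both species, 20 of them higher in both and 20 lower in both, where independent lists would share 26.8 and 16.6. At 15 min 247 were called in both, 120 higher in both and 46 lower in both, where independent lists would share 85.4 and 18.1. At 30 min 688 pairs were called in both species, 438 of them in the same direction. Of these 364 were higher in both, where independent lists would share 358.5, and 74 lower in both, where they would share 35.2.

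**Figure D3:**
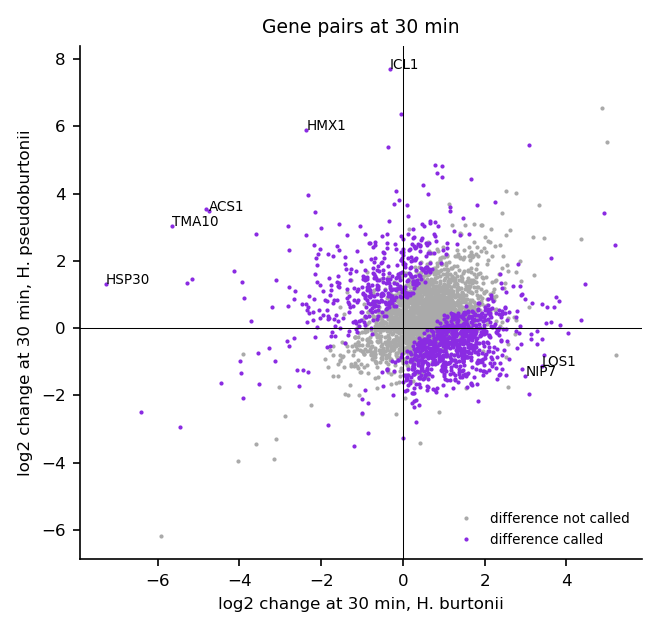
Log2 change at 30 min against 0 min in H. burtonii (horizontal) and H. pseudoburtonii (vertical), 1 point per gene pair, with pairs whose difference was called in purple. HMX1, TMA10, ACS1 and HSP30 lay far above the diagonal, with differences of 8.26, 8.67, 8.22 and 8.57, and NIP7 and LOS1 below it.

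**Figure D4:**
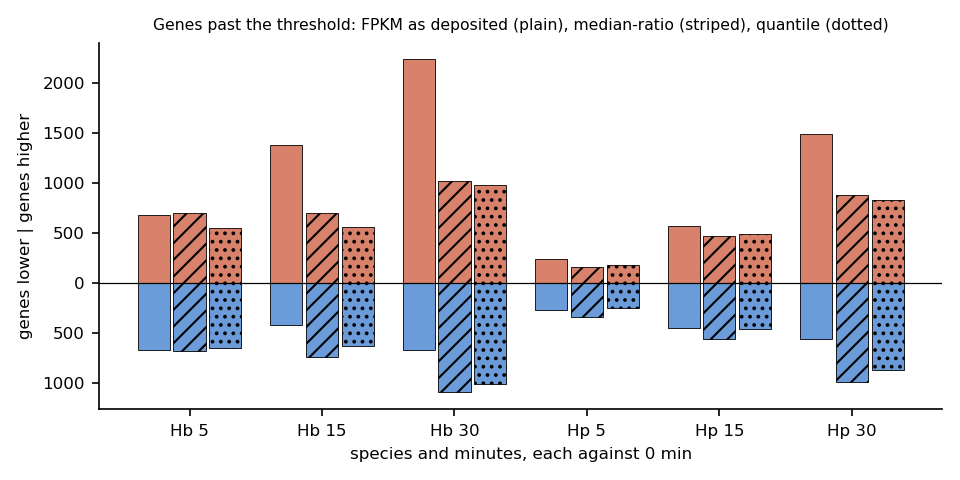
Genes called higher (up) and lower (down) against 0 min in each species, in FPKM as deposited and after median-ratio and quantile scaling. At 30 min the excess of higher over lower genes in H. burtonii, 2236 against 671, turned to 1022 against 1092 and 983 against 1012.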

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

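The tests of a 0 min library standing apart, gene length, wrong pairing, replicate noise and added medium were written before their values were computed, and those of harvest times out of step, FPKM scaling and shared reads were written after the result was seen.

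The changes differed between the species for 528 pairs at 5 min, 707 at 15 min and 1227 at 30 min, which is a difference between groups. At 5 min RGI1 differed by -6.81, STO1 (TBIG000146 and TBIG005381) at -6.77, sre1 (TBIG005586 and TBIG001775) at -6.60, TYE7 at -6.50 and ERG25 (TBIG004685 and TBIG004436) at -5.50. At 15 min ALR2 differed by -5.40, CTR3 by 4.78, STO1 at -4.62 and MLS1 by 3.88. At 30 min TMA10 differed by 8.67, HSP30 by 8.57, put4 by 8.37, HMX1 by 8.26, ACS1 by 8.22, MLS1 by 6.61, LOS1 at -4.54 and NIP7 at -4.44. A constant shift between the library series cancels in these differences of changes. An effect of depth would not, as estimated depth changed with time in opposite directions in the species. Each species is 1 strain here, so a difference between the species cannot be told apart from one between the strains.

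The changes of the species were hardly related across the 3399 tested gene pairs. Genes whose annotation recurs within a species are not among these, and the glycerol list kept 5 pairs. Wrong pairing throughout would leave levels at 0 min unrelated, but these correlated at r = 0.659. That leaves room for some pairs that join paralogs. Replicate noise would leave changes from separate replicates unrelated, but the lowest of these r was 0.585. Whether the replicates were separate cultures is not known, so variation between cultures may not be covered. Harvest times out of step would give a high r between different times. The highest was 0.193, for H. burtonii at 30 min against H. pseudoburtonii at 5 min. It lay above the r at equal times (0.021, 0.132 and 0.068 at 5, 15 and 30 min), the direction such a shift predicts. No sampled times gave a high r, but offsets outside the sampled times cannot be seen here. A shift in timing and a difference between the strains or species stay open.

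Ribosome biogenesis genes were higher at 5 min in both species. A 0 min library standing apart would remove the shift, but the lowest list median without 1 of the 4 was 0.441 above all genes. Gene length would give other genes of that length the same shift, but the list lay at least 0.435 above 50 length-matched genes. Added fresh medium could also raise these genes, and with 0 libraries given medium without salt the 2 causes cannot be told apart.

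Glycolysis genes were lower in both species. FPKM scaling could lower them, but in H. burtonii at 15 and 30 min and H. pseudoburtonii at 5 and 15 min the highest value under the other scalings was -0.739 from all genes. In H. pseudoburtonii at 30 min it was -0.255, which leaves scaling open there. Reads shared between copies could shift single genes, but with copies summed over 15 enzymes the highest median was -1.235 from all genes. This version replaced a first one that kept only members whose gene name occurs once. Its highest value was -0.715, in H. pseudoburtonii at 30 min (17 of 22 members). Added fresh medium cannot be told apart from salt, with 0 libraries given medium alone.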

How the results depend on the processing

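Leaving out 2 libraries together, and the other 4 added alternatives, were chosen after the data were seen, and the rest before. Across 281 printed changes of single genes and pairs and 4797 alternatives, 4611 values kept their direction and side of the threshold, 135 lost and 30 gained a call and 21 turned direction. The tables hold no counts and 2 libraries per group, so counts of calls depend on single libraries. At log2 1 the test found far fewer genes than at 2 in simulated data, and estimated depth in H. pseudoburtonii went down to 0.267 of its deepest library. The cause was not tested for any value below except where fewer libraries entered a fit.

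Directions turned for genes that were not called or barely so. HSP104 of H. burtonii at 15 min was -0.062 with median-ratio scaling, -0.231 without 0 min replicate 1 and -0.160 without 15 min replicate 2, in a range up to 0.834. HOG1 at 5 min was 0.061 with quantile scaling and between -0.211 and 0.032 without 1 library. RCN1 at 30 min was -0.050 with median-ratio scaling, and GPD (TBIG002932) was 0.464 with quantile scaling. GPD (TBIG005904) of H. burtonii at 15 min was -0.230 with median-ratio scaling and ranged from -0.109 to 0.376 without 1 library, with -0.004 without 15 min replicate 1. STL1 (TBIG002607) at 30 min ranged from -1.198 to 0.235 and STL1 (TBIG005322) from -0.125 to 0.051, each highest without 0 min replicate 2, and STL1 (TBIG002606) at 5 min from -0.358 to 0.615. In H. pseudoburtonii ACT1 was 0.307 at 5 min and 0.20 at 15 min with quantile scaling, and ranged from -0.091 to 0.038 at 5 min without 1 library. ENA5 (TBIG000534) at 5 min ranged from -0.753 to 0.092 and HSP12 from -0.261 to 0.582, the lowest also with 5 min replicate 2 and 15 min replicate 1 left out together. HOG1 at 15 min ranged from -0.653 to 0.034, the highest again with those 2 left out together.

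Called genes against 0 min ranged without 1 library from 178 to 1647, 913 to 2025 and 1785 to 3023 at 5, 15 and 30 min in H. burtonii and from 100 to 679, 272 to 1166 and 918 to 2371 in H. pseudoburtonii. Between 5 and 15 min they ranged from 120 to 1590 and from 91 to 356, and between 15 and 30 min from 240 to 1239 and from 22 to 1125. Pairs called for the species difference ranged from 247 to 677 at 5 min, 407 to 787 at 15 min and 885 to 1313 at 30 min. At least 2-fold calls numbered 865 in H. burtonii at 5 min, 681 between 5 and 15 min and 632 between 15 and 30 min. Quantile scaling gave 1179 calls in H. burtonii at 15 min and 698 between 5 and 15 min, where median-ratio scaling gave 673. Without a trend 117 genes were called in H. pseudoburtonii between 5 and 15 min.

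Correlations between the species ranged from -0.018 to 0.060 at 5 min and 0.030 to 0.097 at 30 min without 1 library, with 0.060 at 5 min for the 2 libraries left out together and a Spearman's rho of 0.023 at 30 min. Lists called numbered 7, 12 and 7 in H. burtonii and 3, 3 and 12 in H. pseudoburtonii at 5, 15 and 30 min. With an estimated correlation 0 were called at every time against 0 min, and with fry 18, 20 and 22 and 7, 14 and 22. Without 1 library they ranged from 5 to 9, 11 to 12 and 5 to 8 and from 3 to 5, 2 to 3 and 10 to 13, and quantile scaling gave 5 in H. pseudoburtonii at 5 min.

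Whether replicate numbers pair the samples is open. Deviations of same-numbered libraries of H. burtonii correlated at r = 0.255 (0 and 5 min), 0.562 (0 and 15 min) and 0.247 (5 and 15 min), but between -0.221 and -0.007 with 30 min, and those of H. pseudoburtonii between -0.105 and 0.050. With a replicate block H. burtonii had 1505, 1885 and 3014 called genes at 5, 15 and 30 min, while 333 genes of H. pseudoburtonii were called at 5 min and 148 between 5 and 15 min.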

Other observations

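The oxygen test here was written after the result was seen, as were the list tests between the species and the choice of metal uptake genes.

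In H. burtonii several genes of copper and iron uptake fell, a group outside the fixed lists and without a list test. At 30 min the copper transporter genes CTR1, CTR2 (TBIG004938) and CTR3 lay at -5.46 (SE 0.28), -3.90 (SE 0.46) and -3.91 (SE 0.88) and the iron permease gene FTR1 (TBIG001982), the ferroxidase gene FET3 (TBIG002222) and the reductase gene FRE7 at -4.19 (SE 0.34), -4.66 (SE 0.33) and -3.52 (SE 0.30). CTR3 had 169.8 ± 173 FPKM at 0 min, lay at -5.20 and -2.61 without 0 min replicate 1 and 2 and lost its call without 30 min replicate 2 (-3.83). A second copy each of FTR1 and FET3 was not called. In H. pseudoburtonii CTR1 (-2.93, SE 0.23), CTR2 (-2.09, SE 0.28) and FRE7 (-1.66, SE 0.23) fell, and FET3 (TBIG002793) fell less (-0.59, SE 0.14), a call lost without any 1 of the 0 and 30 min libraries (-0.66 to -0.52). There CTR3, both FTR1 copies and the other FET3 copy were not called.

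Tested on the species difference, glycolysis lay lower in H. pseudoburtonii than in H. burtonii at 5 min (15 pairs, median difference -1.10, camera adjusted p = 2.98e-06, 0.147 with an estimated correlation), as did chaperones (22 pairs, -0.66, adjusted p = 0.000944), ribosome biogenesis (124 pairs, -0.40, 0.00433), ribosomal protein genes (57 pairs, -0.39, 0.00472) and calcineurin and calcium transport (10 pairs, -0.36, 0.0256). Amino acid biosynthesis (61 pairs) lay higher there at 5 min (0.64, adjusted p = 0.000226) and 15 min (0.22, 0.000189), where the median differences over all pairs were 0.05 and -0.325. None of these was called with an estimated correlation. At 30 min ribosomal protein genes (57 pairs, -0.81, 0.581 with an estimated correlation), ribosome biogenesis (-1.11, 45 pairs called, 0.721) and translation factors (37 pairs, -1.21, 0.295) lay lower there, and beta-oxidation (9 pairs, 1.93, 0.0838) and autophagy (25 pairs, 0.90, 0.295) higher. The median difference over all pairs, not taken off here, was -0.28 at that time.

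As a hypothesis, the sterol genes that fell in both species at 30 min, and the lower glycolysis genes of H. burtonii, could follow from less oxygen limitation after fresh medium was added. Other genes raised in low oxygen should then fall in both species at 30 min. Their median lay at -1.341 from all genes in H. burtonii (9 genes, 2 higher, 5 lower) and at -0.082 in H. pseudoburtonii (7 genes, 1 higher, 2 lower). HEM13, of haem synthesis, fell in both (-2.88, SE 0.19 and -2.61, SE 0.20). The 30 min value of H. pseudoburtonii does not meet the prediction and, by the criterion written for the test, counts against the hypothesis. At 5 and 15 min, times outside the prediction, its list lay at -0.677 (0 higher, 3 lower) and -0.647 (0 higher, 1 lower). The list of H. burtonii lay at -0.101 and -1.491 at those times. At 30 min members moved both ways in both species and several shared a name, so a test on so few genes does not settle it. Respiration genes, at first part of it, were left out because in H. burtonii 3 of 29 were higher and 1 lower at 30 min.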
